A study of Mus musculus with 55 samples.

How the data were processed

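The series measured bulk RNA and T cell receptor sequences in tumours grown from BBN963, a mouse bladder cancer line, under the skin of mice given chow with or without entinostat, an inhibitor of class I histone deacetylases. Hosts were C57BL/6 mice, called B6 here, and NSG mice, which lack T, B and NK cells. Of 55 samples, 47 were analysed: 30 RNA-seq libraries and 17 T cell receptor libraries. The other 8 samples were not analysed here, namely the RNA and receptor libraries of 1 entinostat tumour in B6 mice and 6 exome libraries (3 vehicle, 3 entinostat). The submitters' RNA and receptor values do not include that entinostat tumour, so B6 entinostat results rest on 5 of 6 tumours.

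Per the labels, B6 mice were randomized at a tumour volume of 200 mm3, the entinostat dose was 12 mg/kg and entinostat tumours were collected at 100 mm3. The volume at which vehicle and baseline tumours were collected is not stated, so tumour size and treatment cannot be separated. For NSG mice the labels state neither the dose nor any tumour volume. The tumour was taken as the independent unit.

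The RNA values were signal per gene, deposited as DESeq2-normalized gene counts per the submitters' processing notes, with 1 table per host, each normalized on its own. Per the submitters' processing notes, STAR, DESeq2 and the mouse build mm10 were used for these libraries, and no versions are given. Whole reads could not be recovered: in each library 46.3 to 79.3% of values under 10 reads lay within 0.05 read of a whole multiple of the library's unit. Tests that need whole reads were therefore not run. The T cell receptor values were a score, the Morisita index of overlap between the TRA (T cell receptor alpha chain) repertoires of pairs of tumours, deposited as a square table per the labels. A larger index means that 2 tumours share more of their receptor sequences. The depth behind the index is unknown, so its precision rests on the spread among tumours.

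Summed signal per RNA library was 21.23 to 37.25 M (M for mega). The most common low value above 0 (the peak of the density of low values on the log2 scale) was taken as 1 read. It was 0.614 to 3.16 units, which puts the libraries at about 11 to 51.5 M reads. The lowest were NSG_Entinostat_319 at 11 M and entinostat 418 in B6 mice at 13.2 M.

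Gene symbols were taken from a name table by Ensembl ID, which matched 47187 of 47606 IDs. They equalled the symbol in the B6 table for 46501 IDs and in the NSG table for 46969. Coordinates were taken by symbol from a RefSeq gene table of assembly GRCm38, which is the mm10 build.

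From the deposited values, log2 of the value plus 1 was fitted with limma 3.58.1 (R 4.3.3), with a trend in the prior variance and robust empirical Bayes, all 3 groups of a host in 1 fit. Genes with a value of at least 10 in at least 4 libraries (B6) or 5 libraries (NSG) were tested. P-values were adjusted by Benjamini-Hochberg (BH) within a comparison, and genes with an adjusted p under 0.05 were called. P-values reflect the spread among tumours. The difference between hosts in the entinostat response was a contrast of the 2 responses in 1 fit of both tables, in which a constant of each table's normalization drops out. Levels were not compared across tables, except those of Il2rg and Prkdc as a check of the host labels.

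A total of 35 gene lists with 514 genes, for cell types, pathways and drug responses, were tested with limma's camera at a preset correlation of 0.01, with BH over the lists of a comparison. Estimated correlations and fry, another limma set test, were alternatives. The lists, tests, alternatives and the rule for named genes were fixed before the data were examined. That rule took, for entinostat against vehicle in each host, the 8 highest and 8 lowest called log2 fold changes with a mean of at least 50 in the higher group and no overlap between groups, 4 and 4 for the other comparisons, passing over predicted genes and pseudogenes and, for the host difference, with the mean taken in B6 groups and without the overlap condition. It also took the 2 to 4 members of each list with the smallest p, and always Hdac1, Hdac2, Hdac3, Cdkn1a, Cd3e, Cd8a, Foxp3, Ifng, Gzmb, Pdcd1, Cd274, B2m, H2-K1 and Mki67. Il2rg and Prkdc, the genes changed in NSG mice, were read as a check of the host labels, which transcript levels in separately normalized tables cannot settle. Members of the mitochondrial transcript list were in neither table, so that list gave no result.

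Mean TRA indexes within and between groups were compared by exact two-sided permutation of tumour labels, all relabelings counted, with BH over 6 tests (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). Figures used matplotlib 3.10.9.

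The gene and list tests were tested on simulated data with 200 genes changed. In B6 entinostat against vehicle (17053 genes), 59.1% of genes changed 4-fold, 34.3% of those changed 2-fold and 2.99% of those changed 1.5-fold were recovered, with 3 false calls. In NSG entinostat against vehicle (17752 genes), 78.8, 41.8 and 13.4% were recovered, with 2 false calls. In B6 vehicle against baseline, the shares were 66.7, 28.4 and 4.48%, with 2 false calls. For the host difference (18470 genes), they were 45.5, 17.9 and 2.99%, with 2 false calls. The changed list was recovered in each of the 6 comparisons within a host, and 1 of 19 other lists was called in B6 vehicle against baseline and 0 in the others. Genes were simulated independently and the lists were random. The false list calls therefore say nothing about real lists, whose members are correlated (0.931 estimated for fibroblasts and matrix in B6 mice). The 200 changed genes were also far fewer than the 9553 called in B6 entinostat against vehicle.

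Alternatives were pseudocounts of 0.5 and 5, no filter and a filter of 50, quantile, cyclic loess and upper quartile scaling, non-robust empirical Bayes, array weights, a fit of only the groups compared, stricter thresholds, and each library left out in turn. Fits without the libraries richest in muscle transcripts (entinostat 413, baseline 415) and without vehicle 402 and 424 in B6 mice were added after the data were seen.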

Results

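RNA was measured in 15 tumours from B6 mice (4 baseline, 6 vehicle, 5 entinostat) and 15 tumours from NSG mice (5 per group). TRA repertoires were compared in 17 B6 tumours (6 baseline, 6 vehicle, 5 entinostat). RNA libraries held about 11 to 51.5 M reads (M for mega). Il2rg, the shared cytokine receptor chain inactivated in NSG mice, averaged 506.1 ± 477.1 (SD, n = 6) normalized counts in B6 vehicle tumours and 118.1 ± 46.78 (SD, n = 5) in NSG vehicle tumours, in tables each normalized on its own. Prkdc, which carries a point mutation in NSG mice that need not lower its transcript, averaged 514.7 ± 159.0 (SD, n = 6) and 629.3 ± 141.7 (SD, n = 5). In B6 tumours the first principal component held 65.7% of the variance and the second 7.73%.

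The first comparison asked what entinostat changed in tumours of immunocompetent mice. Most genes of the basal and squamous, luminal and epithelial adhesion lists were lower in B6 entinostat than in vehicle tumours. Krt14, a basal keratin (ENSMUSG00000045545, mm10 chromosome 11, 100203162 to 100207510), averaged 170000 ± 119600 (SD, n = 6) normalized counts in vehicle tumours and 175.6 ± 139.4 (SD, n = 5) in entinostat tumours. Cdh1, which encodes E-cadherin, averaged 12830 ± 1604 (SD, n = 6) and 785.2 ± 73.65 (SD, n = 5). Cd68, a macrophage marker, went the other way, from 1055 ± 624.0 (SD, n = 6) to 22930 ± 7142 (SD, n = 5).

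The 3 epithelial lists fell. Of 17 basal and squamous genes tested, 15 fell, 0 rose and 2 did not pass, with a median log2 fold change of -8.37 (camera adjusted p = 1.7e-08, and adjusted p = 0.208 with an estimated correlation). Krt14 fell by 10.12 on the log2 scale, and Krt5 and the cornified envelope gene Ivl had log2 fold changes of -9.55 and -8.19. All 13 epithelial adhesion genes fell, with a median of -5.11 (adjusted p = 4.2e-09, and adjusted p = 0.208 with an estimated correlation). Cdh1 had a log2 fold change of -4.02 (adjusted p = 7.4e-10), Esrp2, an epithelial splicing factor, -5.12, and Epcam -5.99. Of 15 luminal urothelial genes, 12 fell and 2 rose, with a median of -3.58 (adjusted p = 0.000389, and adjusted p = 0.208 with an estimated correlation). Erbb2 was at -2.86 and the urothelial regulators Grhl3 and Foxa1 at -7.75 and -6.86. Of 7 skin keratinocyte genes, 6 fell, with a median of -3.43 (adjusted p = 0.00673, and adjusted p = 0.398 with an estimated correlation), among them Lor at -6.50 and Krt10 at -3.43.

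The 8 lowest genes by the fixed rule included keratins and cornified envelope genes. Fgfbp1, a carrier of fibroblast growth factors (ENSMUSG00000048373, chromosome 5, 43978858 to 43981828), had a log2 fold change of -10.75 (SE 0.79, adjusted p = 9.74e-08), from 6870 ± 5632 (SD, n = 6) to 4.65 ± 7.13 (SD, n = 5) normalized counts. Gpx2, a glutathione peroxidase, was at -10.18, the keratins Krt4, Krt14 and Krt13 at -10.14, -10.12 and -9.92, and Psapl1 at -10.01. Sprr2a2 and Sprr2a3, cornified envelope genes whose near-identical copies share reads, were at -10.27 and -9.98.

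**Figure D1:**
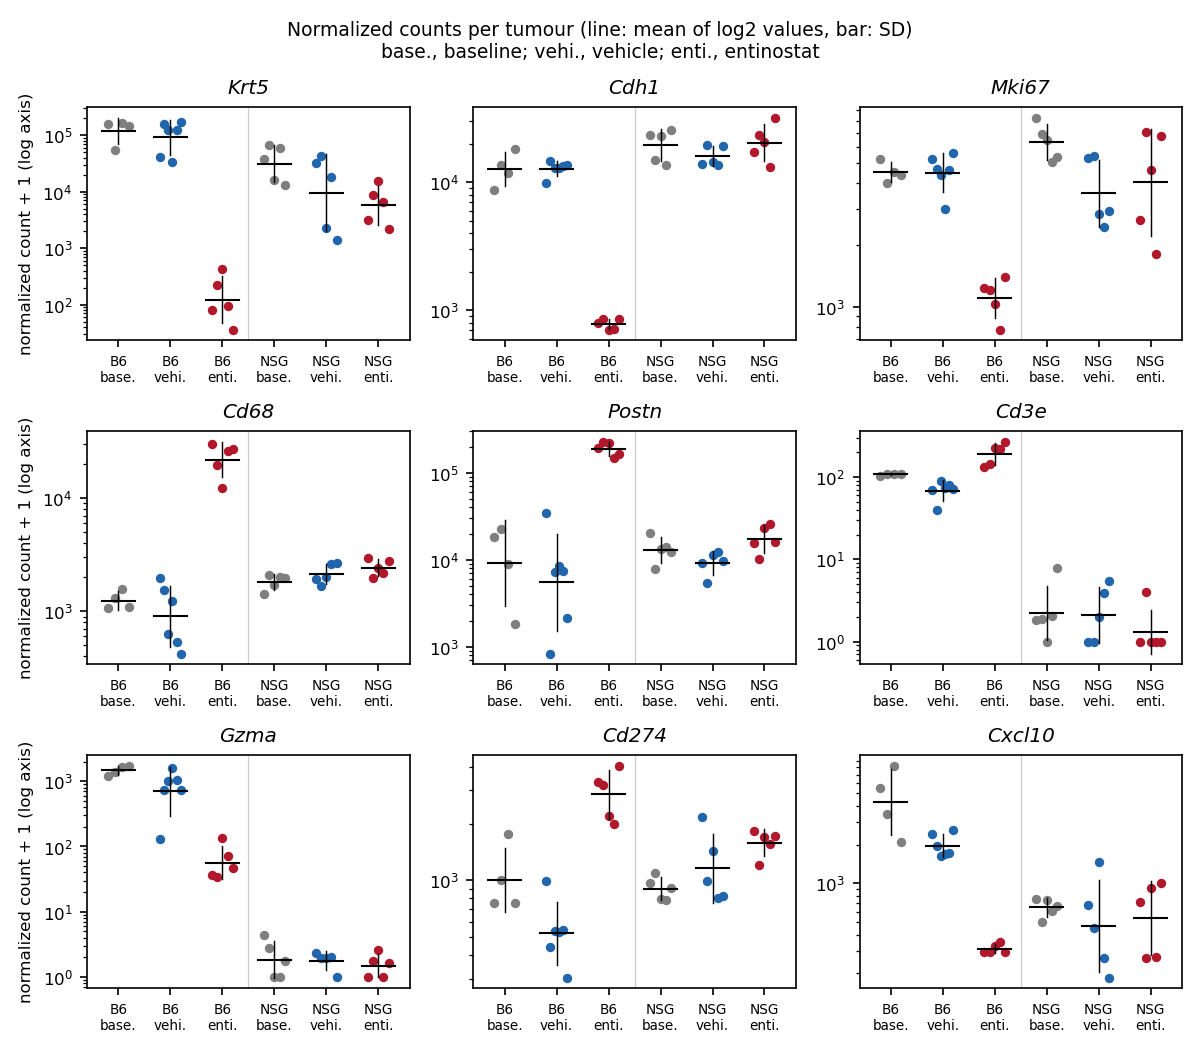
Normalized counts per tumour (log axis) of 9 genes in baseline, vehicle and entinostat tumours of B6 and NSG mice, where each point is 1 tumour, lines are means of log2 values and bars are SD. Krt5 and Cdh1 were lower and Cd68 and Postn higher in B6 entinostat tumours than in B6 vehicle tumours, while in NSG mice no gene passed the test between these groups.

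Myeloid and stromal lists rose as the epithelial lists fell. All 20 macrophage and monocyte genes rose, with a median log2 fold change of 4.36 (camera adjusted p = 1.56e-08, and adjusted p = 0.398 with an estimated correlation). Cd68 rose by 4.60, the lipid receptor gene Trem2 by 6.11 and the scavenger receptor gene Msr1 by 4.67. Of 12 dendritic cell genes, 9 rose and 1 fell, with a median of 2.64 (adjusted p = 0.00471, and adjusted p = 0.43 with an estimated correlation), with Ccl22 at 3.76 and Itgax at 3.70. Of 12 neutrophil genes, 7 rose, with a median of 1.72 (adjusted p = 0.0148, and adjusted p = 0.45 with an estimated correlation), led by Mmp8 at 6.86. Of 11 genes for MHC class II presentation, 10 rose, with a median of 1.67 (adjusted p = 0.000885, and adjusted p = 0.43 with an estimated correlation), with the protease gene Ctss at 4.87 and H2-Aa at 2.08.

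All 20 fibroblast and matrix genes rose, with a median of 4.73 (adjusted p = 2.52e-06, and adjusted p = 0.43 with an estimated correlation). Postn, a matrix protein gene, averaged 10090 ± 12370 (SD, n = 6) in vehicle and 190500 ± 33750 (SD, n = 5) in entinostat tumours, and Thbs2 and Lum rose by 4.20 and 6.22. Of 12 mesenchymal transition genes, 10 rose and 1 fell, with a median of 3.43 (adjusted p = 0.00417, and adjusted p = 0.43 with an estimated correlation), with Zeb2 at 4.05 and Vim at 4.49. All 13 endothelial genes rose, with a median of 2.10 (adjusted p = 0.00382, and adjusted p = 0.45 with an estimated correlation), with Vwf at 2.31 and Tek at 3.81. Of 11 adipocyte genes, 6 rose, with a median of 4.20 (adjusted p = 0.0164, and adjusted p = 0.45 with an estimated correlation), with Lpl at 7.22 and Fabp4 at 4.27. Of 13 skeletal muscle genes, 11 rose, with a median of 7.24 (adjusted p = 0.00214, and adjusted p = 0.45 with an estimated correlation). The muscle signal was uneven: Acta1, skeletal muscle actin, ranged from 55.35 to 132500 normalized counts among entinostat tumours, the highest being tumour 413. None of 5 red cell genes passed, with a list adjusted p = 0.566.

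Lymphocyte lists rose as well. Of 23 T cell genes, 21 rose and 1 fell, with a median of 1.88 (adjusted p = 1.99e-06, and adjusted p = 0.398 with an estimated correlation). Cd28 rose by 3.97 and Icos by 3.60, both costimulatory receptors, and Bcl11b fell by 2.01. Cd3e, a chain of the T cell receptor complex, rose by 1.48 (SE 0.26, adjusted p = 0.000279), from 69.55 ± 17.01 (SD, n = 6) to 196.9 ± 59.29 (SD, n = 5). Of 16 cytotoxic effector genes, 10 rose and 2 fell, with a median of 1.52 (adjusted p = 0.00673, and adjusted p = 0.43 with an estimated correlation). The granzymes went apart. Gzmb rose by 1.89 (SE 0.29, adjusted p = 6.9e-05), from a vehicle mean that lay below the baseline mean. Gzma had a log2 fold change of -3.64, from 877.0 ± 487.4 (SD, n = 6) to 64.32 ± 42.76 (SD, n = 5). Cd8a had a log2 fold change of 0.78 (adjusted p = 0.0913) and Ifng of 0.10 (SE 0.52, adjusted p = 0.883).

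Of 13 checkpoint and exhaustion genes, 11 rose, with a median of 1.91 (adjusted p = 0.000595, and adjusted p = 0.398 with an estimated correlation). Cd274, which encodes PD-L1 (ENSMUSG00000016496, chromosome 19, 29362107 to 29388095), rose by 2.45 (SE 0.29, adjusted p = 8.4e-06), from 556.2 ± 230.5 (SD, n = 6) to 2963 ± 853.7 (SD, n = 5). Ctla4, Havcr2 and Pdcd1, inhibitory receptors of T cells, rose by 3.08, 2.89 and 2.01. Of 9 regulatory T cell genes, 7 rose and 1 fell, with a median of 1.83 (adjusted p = 0.0219, and adjusted p = 0.208 with an estimated correlation), with Il2ra at 3.24 and Tnfrsf4 at 2.40. Foxp3, which specifies these cells, rose by 1.07 (SE 0.39, adjusted p = 0.0294), a call lost at log2 fold change 0.90 with quantile scaling. Of 13 B and plasma cell genes, 10 rose, with a median of 3.89 (adjusted p = 0.00149, and adjusted p = 0.43 with an estimated correlation), with Cd22 at 4.83 and Tnfrsf17 at 3.77. Antibody signal was uneven: kappa chain variable segments summed to 363 to 16300 normalized counts among entinostat tumours. They summed to 1290 in vehicle 402 and to 2.28 to 122 in the other vehicle tumours. Of 8 NK cell genes, 4 rose and 1 fell, with a list adjusted p = 0.0672.

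Interferon response lists fell. Of 18 interferon gamma response genes, 12 fell and 1 rose, with a median of -1.45 (adjusted p = 0.000266, and adjusted p = 0.43 with an estimated correlation). The chemokine gene Cxcl10 had a log2 fold change of -2.67 (adjusted p = 1.6e-06), from 2000 ± 409.1 (SD, n = 6) to 310.1 ± 26.18 (SD, n = 5), and the GTPase gene Irgm1 was at -1.59. Of 23 type I interferon response genes, 16 fell, with a median of -1.52 (adjusted p = 0.000243, and adjusted p = 0.45 with an estimated correlation), among them Ifi44 at -3.59 and Xaf1 at -1.83. Of 17 genes for MHC class I presentation, 8 fell and 1 rose, with a list adjusted p = 0.0989. The peptide transporter gene Tap1 was at -1.07 and the immunoproteasome gene Psmb8 at -0.85. B2m had a log2 fold change of 0.33 (adjusted p = 0.192) and H2-K1 of -0.45 (adjusted p = 0.0442), a call lost at -0.27 with cyclic loess scaling.

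Proliferation and hypoxia lists fell. Of 24 cell cycle genes, 22 fell and 1 rose, with a median of -2.22 (adjusted p = 1.21e-11, and adjusted p = 0.208 with an estimated correlation). Cdc20 was at -3.12 and Top2a at -2.61. Mki67, the proliferation marker, had a log2 fold change of -2.02 (SE 0.18, adjusted p = 4.46e-07), from 4569 ± 893.0 (SD, n = 6) to 1124 ± 236.6 (SD, n = 5). Of 16 hypoxia and glycolysis genes, 13 fell and 1 rose, with a median of -1.52 (adjusted p = 0.000243, and adjusted p = 0.398 with an estimated correlation), with Egln3 at -4.69 and Pdk1 at -2.15.

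Genes tied to the drug's targets, and those of several other lists, moved both ways. Hdac1, a target of entinostat, had a log2 fold change of -0.60 (SE 0.15, adjusted p = 0.00416), Hdac2 of -0.65 (adjusted p = 0.0756) and Hdac3 of -0.46 (adjusted p = 0.114). Of 11 histone deacetylase genes, 3 rose and 3 fell (list adjusted p = 0.566), with Hdac6 at -0.97 and Hdac9 at 3.19. Of 11 genes reported to respond to these inhibitors, 4 rose and 2 fell (list adjusted p = 0.866), with Gsn at 2.82 and H1f0 at -1.37. Cdkn1a, the cell cycle inhibitor p21, had a log2 fold change of 0.16 (adjusted p = 0.73). Among 7 CDK inhibitor genes, 1 rose, Cdkn1c at 3.28, and 2 fell, Cdkn2a at -3.16 and Cdkn2b at -0.84 (list adjusted p = 0.927). Of 20 chemokine genes, 11 rose and 4 fell (median 2.09, adjusted p = 0.0299, and adjusted p = 0.45 with an estimated correlation), with Cxcl16 at 1.46 and Ccl3 at 3.00. Of 14 inflammatory cytokine genes, 4 rose and 4 fell (adjusted p = 0.811), with Lif at -2.64 and Osm at 2.31. Of 13 p53 targets, 3 rose and 3 fell (adjusted p = 0.948), with Gtse1 at -2.10 and Bbc3 at 1.78. Of 13 immediate early genes, 4 rose and 4 fell (adjusted p = 0.811), with Atf3 at 3.98 and Egr1 at -1.52.

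The 8 highest genes were of several tissues. Npy, a neuropeptide (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507), rose by 9.98 on the log2 scale (SE 0.94, adjusted p = 8.65e-07), from 0.846 ± 1.04 (SD, n = 6) to 2520 ± 1719 (SD, n = 5) normalized counts. Cd36, a fatty acid transporter (ENSMUSG00000002944, chromosome 5, 17781690 to 17888959), rose by 8.85 (SE 0.85, adjusted p = 1.15e-06), from 176.5 ± 181.3 (SD, n = 6) to 55780 ± 29810 (SD, n = 5). Tnn, a tenascin of the matrix, rose by 8.97, Mamdc2 by 8.85 and the elongation factor gene Eef1a2 by 8.48. The muscle genes Acta1, Ckm and Pvalb rose by 9.03, 8.49 and 8.38.

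**Figure D2:**
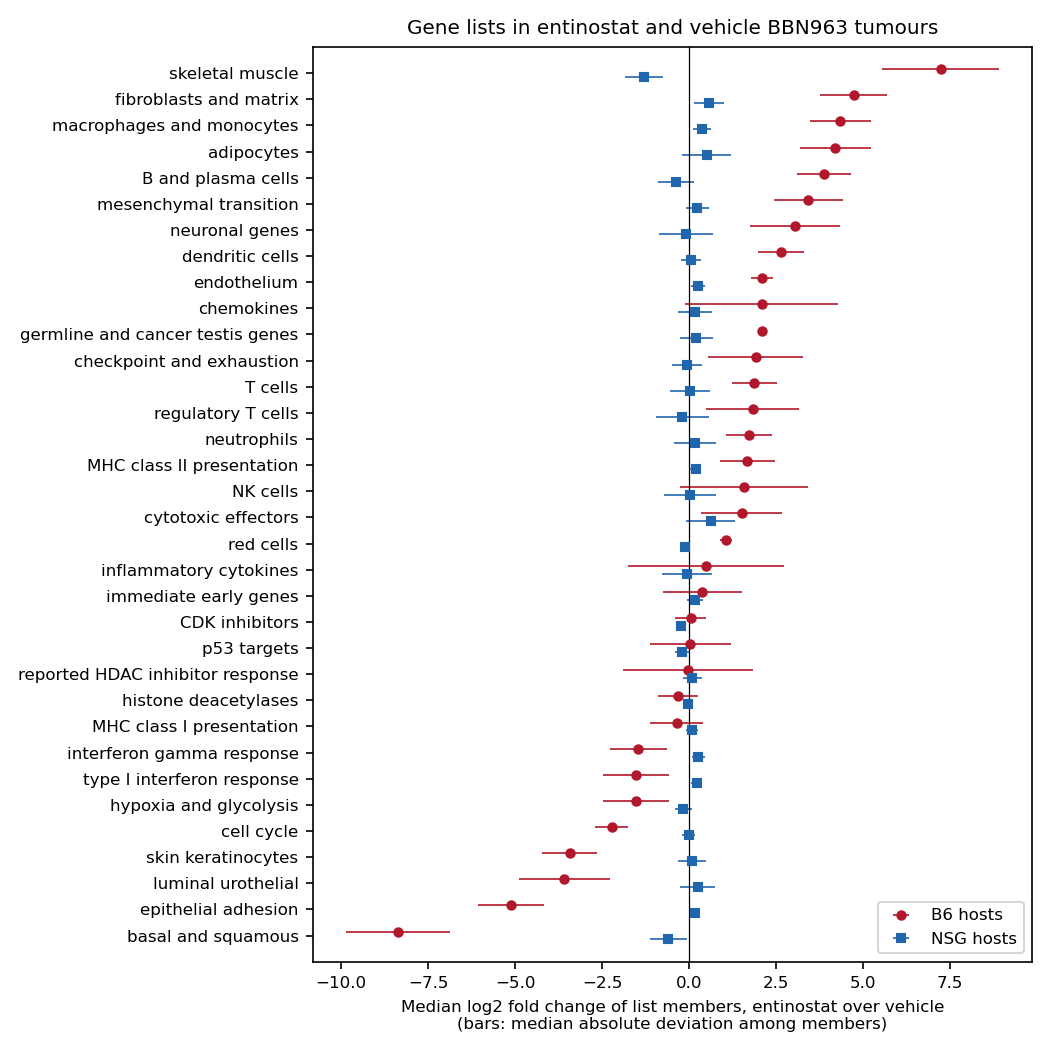
Median log2 fold change of each gene list, entinostat over vehicle, in B6 and NSG tumours, with bars for the median absolute deviation of its members. The basal and squamous list lay at -8.37 and the fibroblast list at 4.73 in B6 tumours, and the fibroblast list at 0.57 in NSG tumours.

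By limma, 9553 of 17053 genes (56.0%) passed in B6 entinostat against vehicle, 5093 higher and 4460 lower, of which 4009 and 2687 differed at least 2-fold. The balance of the 2 directions turned with the scaling, to 4548 higher and 5305 lower with quantile and 4643 and 5033 with cyclic loess scaling. Adjusted over the list alone, the counts were as given except for B and plasma cells (11 rose), neutrophils (9), dendritic cells (10), mesenchymal transition (11), skeletal muscle (12), chemokines (13), interferon gamma response (14 fell), type I interferon response (17 fell), skin keratinocytes (7 fell) and CDK inhibitors (1 fell). Of the 25 lists called with the preset correlation, 0 were called with an estimated correlation, and all 25 were called with fry (adjusted p up to 0.00805). Without the libraries richest in muscle transcripts, 8737 genes passed.

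B6 entinostat tumours were also compared with tumours taken at baseline. Basal and squamous genes were lower, 15 of 17, with a median log2 fold change of -9.57 (camera adjusted p = 5.72e-09, and adjusted p = 0.302 with an estimated correlation), and Krt14 was at -10.71. All 13 epithelial adhesion genes fell, with a median of -4.72 (adjusted p = 5.72e-09, and adjusted p = 0.251 with an estimated correlation), with Cdh1 at -4.01. Of 20 macrophage genes, 19 rose (20 adjusted over the list alone), with a median of 3.84 (adjusted p = 1.23e-07, and adjusted p = 0.434 with an estimated correlation), and all 20 fibroblast genes rose, with a median of 4.01 (adjusted p = 2.6e-05, and adjusted p = 0.511 with an estimated correlation). Of 23 T cell genes, 14 rose and 1 fell (15 and 1 adjusted over the list alone), with a median of 1.04 (adjusted p = 0.00202, and adjusted p = 0.511 with an estimated correlation), with Cd28 at 3.19. Of 18 interferon gamma response genes, 15 fell (16 adjusted over the list alone), with a median of -1.87 (adjusted p = 5.59e-06, and adjusted p = 0.434 with an estimated correlation), with Cxcl10 at -3.78. Of 24 cell cycle genes, 22 fell and 1 rose, with a median of -2.41 (adjusted p = 4.73e-13, and adjusted p = 0.251 with an estimated correlation), with Cdc20 at -3.46. Of 17 genes for MHC class I presentation, 10 fell, with a median of -0.55 (adjusted p = 0.0282, and adjusted p = 0.511 with an estimated correlation), with Tap1 at -1.53. The other 16 lists called had medians of -5.38 (skin keratinocytes), -3.08 (luminal urothelial), -1.71 (type I interferon response), -1.48 (hypoxia and glycolysis), 1.01 (MHC class II presentation), 1.49 (checkpoint and exhaustion), 1.80 (endothelium), 1.99 (neutrophils), 2.21 (germline and cancer testis genes), 2.23 (dendritic cells), 2.48 (chemokines), 3.26 (B and plasma cells), 3.28 (mesenchymal transition), 3.51 (neuronal genes), 5.12 (adipocytes) and 5.20 (skeletal muscle). Their adjusted p was 0.00012 to 0.0383 by camera, and adjusted p = 0.302 to 0.66 with an estimated correlation. Gzma was at -4.71, and the cytotoxic effector list did not pass (adjusted p = 0.327).

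Among the highest genes by the rule were Cd36 at 8.03 (adjusted p = 9.65e-06), Npy at 7.56 and the growth factor gene Gdf10 at 7.34. The lowest were BC100530 at -11.43 (adjusted p = 0.000141), Fgfbp1 at -11.21, the keratin Krt6b at -10.89 and the desmosomal cadherin Dsc3 at -10.86. By limma, 9284 of 17053 genes (54.4%) passed, 4965 higher and 4319 lower (4554 and 5073 with quantile and 4469 and 4785 with cyclic loess scaling), and 24 lists were called with the preset correlation and 0 with an estimated one.

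Vehicle and baseline tumours of B6 mice were compared to show what growth without the drug changed. Gzmb averaged 576.8 ± 124.7 (SD, n = 4) in baseline and 147.3 ± 49.84 (SD, n = 6) in vehicle tumours, a log2 fold change of -2.0 (SE 0.31, limma adjusted p = 0.148). Its rise of 1.89 in entinostat over vehicle tumours was close in size to this difference, so it does not show a rise above baseline. By limma, 0 of 17053 genes passed, 749 had an unadjusted p under 0.05 where chance gives 853, and the smallest adjusted p was 0.148. Camera called 13 lists at the preset correlation. The T cell list had a median of -0.78 (adjusted p = 5.35e-13, and adjusted p = 0.28 with an estimated correlation), and its members with the smallest p were Cd2 at -1.33 and Trac at -1.03. The cytotoxic effector list had a median of -0.94 (adjusted p = 2.28e-10, and adjusted p = 0.233 with an estimated correlation), and 2 of its 16 genes fell adjusted over the list alone. The interferon gamma response list had a median of -0.57 (adjusted p = 3.39e-07, and adjusted p = 0.512 with an estimated correlation) and 1 gene fell adjusted over the list alone, and the regulatory T cell list one of -0.57 (adjusted p = 0.0018, and adjusted p = 0.0954 with an estimated correlation) and 3 genes. The other 9 lists called, with no member called, had medians of -1.87 (skeletal muscle), -0.64 (MHC class II presentation), -0.62 (basal and squamous), -0.51 (NK cells), -0.49 (checkpoint and exhaustion), -0.285 (cell cycle), -0.27 (immediate early genes), -0.24 (MHC class I presentation) and 1.07 (red cells). Their adjusted p was 5.18e-06 to 0.0359 by camera, and adjusted p = 0.512 to 0.814 with an estimated correlation. With array weights 2756 genes passed, and without vehicle 405, 2 genes passed.

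In NSG mice, entinostat and vehicle tumours were compared to show what the drug changed without T, B and NK cells. No gene passed the test. Cdh1 averaged 16130 ± 2976 (SD, n = 5) in vehicle and 21280 ± 7077 (SD, n = 5) in entinostat tumours, Krt5 19350 ± 18220 (SD, n = 5) and 7273 ± 5354 (SD, n = 5), and Cd68 2176 ± 438.3 (SD, n = 5) and 2453 ± 405.8 (SD, n = 5). Mki67 had a log2 fold change of 0.17 (SE 0.34, adjusted p = 0.906), Cd274 of 0.45 (adjusted p = 0.696), Cdkn1a of -0.27 (adjusted p = 0.774), and Hdac1, Hdac2 and Hdac3 of -0.03, 0.07 and -0.26. Foxp3 was at -0.31, B2m at 0.03 and H2-K1 at 0.09. Cd3e, Cd8a, Gzmb and Pdcd1 lay below the filter, and Ifng was listed at 0 in all 15 NSG libraries.

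Camera called 8 lists at the preset correlation, with 0 members called. The fibroblast list had a median of 0.57 (adjusted p = 6.15e-08, and adjusted p = 0.777 with an estimated correlation), and 3 of its 20 genes rose adjusted over the list alone, with Pdgfra at 0.91. The macrophage list had a median of 0.36 (adjusted p = 1.29e-05, and adjusted p = 0.777 with an estimated correlation), with Mrc1 at 1.15. The type I interferon list had a median of 0.22 (adjusted p = 0.014, and adjusted p = 0.935 with an estimated correlation), and the skeletal muscle list one of -1.29 (adjusted p = 0.0394, and adjusted p = 0.935 with an estimated correlation). The other 4 lists called had medians of 0.17 (epithelial adhesion), 0.24 (mesenchymal transition), 0.26 (endothelium) and 0.63 (3 cytotoxic effector genes), with a camera adjusted p of 0.0332 to 0.0473, and adjusted p = 0.562 to 0.935 with an estimated correlation. By limma, 0 of 17752 genes passed, 1287 had an unadjusted p under 0.05 where chance gives 888, and the smallest adjusted p was 0.168. With array weights and without NSG_Non-Treatment_302, a vehicle library, 1 gene passed each time.

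NSG entinostat tumours differed from baseline tumours in 13 lists by camera, among them those of neutrophil and dendritic cell genes. Of 12 neutrophil genes, 4 rose (5 adjusted over the list alone), with a median log2 fold change of 0.61 (camera adjusted p = 0.0127, and adjusted p = 0.601 with an estimated correlation), with Retnlg at 4.25, S100a8 at 2.40, Ly6g at 2.31 and S100a9 at 1.79. Of 12 dendritic cell genes, 2 fell (8 adjusted over the list alone), Itgax at -2.79 and Ccr7 at -2.19, with a median of -1.90 (adjusted p = 6.01e-06, and adjusted p = 0.351 with an estimated correlation). The list for MHC class II presentation had a median of -1.22 (adjusted p = 0.000383, and adjusted p = 0.601 with an estimated correlation), with 0 of 10 genes called and 6 lower adjusted over the list alone. The other 10 lists called had medians of -2.87 (skin keratinocytes), -2.645 (skeletal muscle), -1.88 (adipocytes), -1.50 (basal and squamous), -0.41 (endothelium), -0.40 (fibroblasts and matrix), 0.275 (epithelial adhesion), 0.32 (hypoxia and glycolysis), 0.355 (MHC class I presentation) and 0.42 (type I interferon response). Their adjusted p was 0.00331 to 0.0257 by camera, and adjusted p = 0.601 with an estimated correlation. The highest genes were Stfa2, a protease inhibitor gene of myeloid cells, at 5.20 (adjusted p = 0.0304), the transcription factor gene Pou3f2 at 5.12, Sult1c2 at 4.48 and Retnlg. The lowest were the major urinary protein genes Mup10 at -5.99 (adjusted p = 0.0472) and Mup17 at -5.34, the trypsinogen gene Prss2 at -4.07 and B3galt5 at -3.25. Members of the Mup and Stfa families share reads.

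By limma, 72 of 17752 genes passed, 37 higher and 35 lower, while 4501 had an unadjusted p under 0.05. The count rested on single libraries: 0 genes passed without NSG_Baseline_303, NSG_Baseline_304, NSG_Baseline_305, NSG_Baseline_320, NSG_Entinostat_306 or NSG_Entinostat_312, 1 without NSG_Baseline_316 or NSG_Entinostat_319, 46 without NSG_Entinostat_315, and 877 without NSG_Entinostat_327.

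By camera, lists of antigen-presenting and stromal cell genes were lower in NSG vehicle than in baseline tumours, calls lost with an estimated correlation. Of 12 dendritic cell genes, 9 fell (10 adjusted over the list alone), with a median of -1.87 (camera adjusted p = 1.23e-05, and adjusted p = 0.235 with an estimated correlation), with Irf8 at -1.16 and Ccr7 at -2.38. Of 10 genes for MHC class II presentation, 7 fell (8 adjusted over the list alone), with a median of -1.40 (adjusted p = 3.27e-05, and adjusted p = 0.53 with an estimated correlation). H2-Aa averaged 2674 ± 595.2 (SD, n = 5) in baseline and 936.6 ± 385.0 (SD, n = 5) in vehicle tumours. Of 20 fibroblast genes, 9 fell (13 adjusted over the list alone), with a median of -0.95 (adjusted p = 1.29e-06, and adjusted p = 0.53 with an estimated correlation), with Thbs2 at -1.57 and Col1a2 at -1.62. Of 13 endothelial genes, 6 fell (9 adjusted over the list alone), with a median of -0.75 (adjusted p = 0.000569, and adjusted p = 0.53 with an estimated correlation), and of 20 macrophage genes 5 fell (6 adjusted over the list alone), with a median of -0.59 (adjusted p = 0.000346, and adjusted p = 0.62 with an estimated correlation). Of 16 hypoxia and glycolysis genes, 5 rose (7 adjusted over the list alone), with a median of 0.58 (adjusted p = 0.000265, and adjusted p = 0.53 with an estimated correlation), with Ankrd37 at 1.23 and Bnip3 at 1.20. The other 5 lists called had medians of -2.68 (adipocytes), -2.51 (skin keratinocytes), -1.01 (basal and squamous), -0.89 (3 cytotoxic effector genes) and -0.65 (mesenchymal transition), with a camera adjusted p of 0.00555 to 0.0469, and adjusted p = 0.235 to 0.794 with an estimated correlation.

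The highest genes were Stfa2 at 4.53 (adjusted p = 0.014), Retnlg at 3.48, Stfa2l1 at 3.16 and Pcp4l1 at 2.84, and the lowest were Mup10 at -6.56 (adjusted p = 0.0169), Mup17 at -5.48, Mup9 at -4.73 and the lectin gene Cd209a at -2.78. By limma, 2312 of 17752 genes (13%) passed, 1336 higher and 976 lower. The count was 0 without NSG_Baseline_303, 43 without NSG_Baseline_305, 808 without NSG_Baseline_320, and, among vehicle libraries, 1487 without NSG_Non-Treatment_311, 292 without NSG_Non-Treatment_323 and 44 without NSG_Non-Treatment_326. Libraries of NSG tumours came from more than 1 sequencing sheet. Baseline and vehicle libraries both hold sheet positions 13 to 16, and libraries at the same position were on different sheets. Which library was on which sheet is not stated, so batch and group cannot be told apart in the NSG comparisons.

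The response to entinostat was then compared between hosts. The labels give no dose or tumour volume for NSG mice, so differences in dose or tumour size cannot be separated from host. In the epithelial adhesion list, the only list called with an estimated correlation, all 13 genes had a lower log2 fold change in B6 than in NSG mice, with a median difference of -5.07 (camera adjusted p = 2.31e-14, and adjusted p = 0.0152 with an estimated correlation). The basal and squamous list differed by -7.63 (adjusted p = 1.84e-08, and adjusted p = 0.254 with an estimated correlation), the cell cycle list by -2.21 (adjusted p = 5.82e-14, and adjusted p = 0.163 with an estimated correlation) and the interferon gamma response list by -1.66 (adjusted p = 0.000109, and adjusted p = 0.414 with an estimated correlation). The macrophage list differed by 3.85 (adjusted p = 1.99e-09, and adjusted p = 0.296 with an estimated correlation), the fibroblast list by 4.13 (adjusted p = 1.79e-06, and adjusted p = 0.419 with an estimated correlation) and the T cell list by 2.0 (adjusted p = 0.000189, and adjusted p = 0.288 with an estimated correlation). NSG mice lack T cells and only 13 of the 23 T cell genes passed the filter there, so that difference does not show a different drug response.

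The largest positive differences, B6 minus NSG, were in Pvalb at 11.38 (SE 2.43, adjusted p = 5.25e-04), Npy at 10.54, Ckm at 10.40 and Acta1 at 10.36. The largest negative were in Sprr2a2 at -9.90, the basal keratin Krt15 at -9.81 (SE 1.01, adjusted p = 2.63e-08), Sprr2a3 at -9.73 and the desmosomal gene Pkp1 at -9.55. Mki67 differed by -2.20 (adjusted p = 8.8e-05), Cd274 by 2.0 (adjusted p = 1.85e-04) and Hdac1 by -0.57 (adjusted p = 0.0166). By limma, 7635 of 18470 genes (41.3%) differed between hosts, 4344 with a higher and 3291 with a lower fold change in B6 mice (3776 and 4153 with quantile scaling). Of 16335 genes tested in both hosts, 4617 rose and 4413 fell in B6 and 0 in NSG mice, so no overlap could be tested. Across those genes, which are not independent replicates, the fold changes of the 2 hosts had a Pearson r of 0.249. Genes called in B6 mice had a median absolute log2 fold change of 1.55 in B6 and 0.192 in NSG mice, and 58.3% had the same sign.

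TRA repertoires were compared to ask whether tumours of a treatment shared T cell clones. Pairs of entinostat tumours had a mean Morisita index of 0.101 ± 0.101 (SD, 10 pairs of 5 tumours), pairs of vehicle tumours one of 0.00500 ± 0.00321 (SD, 15 pairs of 6 tumours) and pairs of baseline tumours one of 0.0372 ± 0.0269 (SD, 15 pairs of 6 tumours). The index within entinostat exceeded that within vehicle by 0.0963 (exact two-sided permutation p = 0.0152, adjusted p = 0.0286, 462 relabelings), a call lost on the log10 scale (0.986, adjusted p = 0.0909). Leaving out any 1 of the 6 vehicle tumours left a difference of 0.0951 to 0.0975 and moved its adjusted p to between 0.0541 and 0.0606, while leaving out any 1 entinostat tumour kept it between 0.00714 and 0.04, with differences of 0.0617 without 413 and 0.160 without 421. Vehicle pairs lay below baseline pairs by a difference of -0.0322 (exact p = 0.0216, adjusted p = 0.0286, 924 relabelings), a call lost without baseline 415 (-0.0251, adjusted p = 0.0584) and without vehicle 402, 405, 408, 414 or 424 (-0.0327 to -0.031, adjusted p = 0.0541 to 0.0606). The index within entinostat exceeded that within baseline by 0.0641 (exact p = 0.0541, adjusted p = 0.0541), which did not pass. It passed without entinostat 421 (0.128, adjusted p = 0.00714) or 418 (0.075, adjusted p = 0.0333), and was 0.0296 without 413.

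The mean index within groups exceeded that between groups in each of the 3 comparisons, although vehicle pairs alone lay below the pairs between groups. Entinostat and vehicle pairs had a mean index of 0.0164, 0.0367 below the mean within groups (exact permutation p = 0.0152, adjusted p = 0.0286). Entinostat and baseline pairs had 0.0252, which was 0.0440 below (exact permutation p = 0.00649, adjusted p = 0.0286), and vehicle and baseline pairs 0.0130, which was 0.00812 below (exact permutation p = 0.0238, adjusted p = 0.0286). Entinostat tumour 421 stood apart, with a mean index to its group of 0.00571 against 0.0848 to 0.153 for the other 4. Without it the entinostat differences became 0.0650 (vehicle) and 0.0703 (baseline), and without 413 they became 0.0216 and 0.0265. The entinostat and vehicle call was lost without any 1 of the 6 vehicle tumours, at differences of 0.0349 to 0.0426 (adjusted p = 0.0541 to 0.0606), and on the log10 scale (0.114, adjusted p = 0.0693). The vehicle and baseline call was lost without vehicle 402, 405, 408, 414 or 424 (0.00666 to 0.00787, adjusted p = 0.0541 to 0.0606) or baseline 415 (0.00464, adjusted p = 0.0844), 419 (0.0061, adjusted p = 0.0805) or 422 (0.00604, adjusted p = 0.0675), and its difference was 0.0136 without baseline 426. It was also lost on the log10 scale (0.0812, adjusted p = 0.158), with the median over pairs (0.00739, adjusted p = 0.0541) and with only tumours that have RNA (0.00826, adjusted p = 0.0686). All entinostat libraries carried 1 index of the i5 kind and all others a different one, so only vehicle and baseline were compared within 1 such index, and the labels do not say whether the libraries were prepared together.

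**Figure D3:**
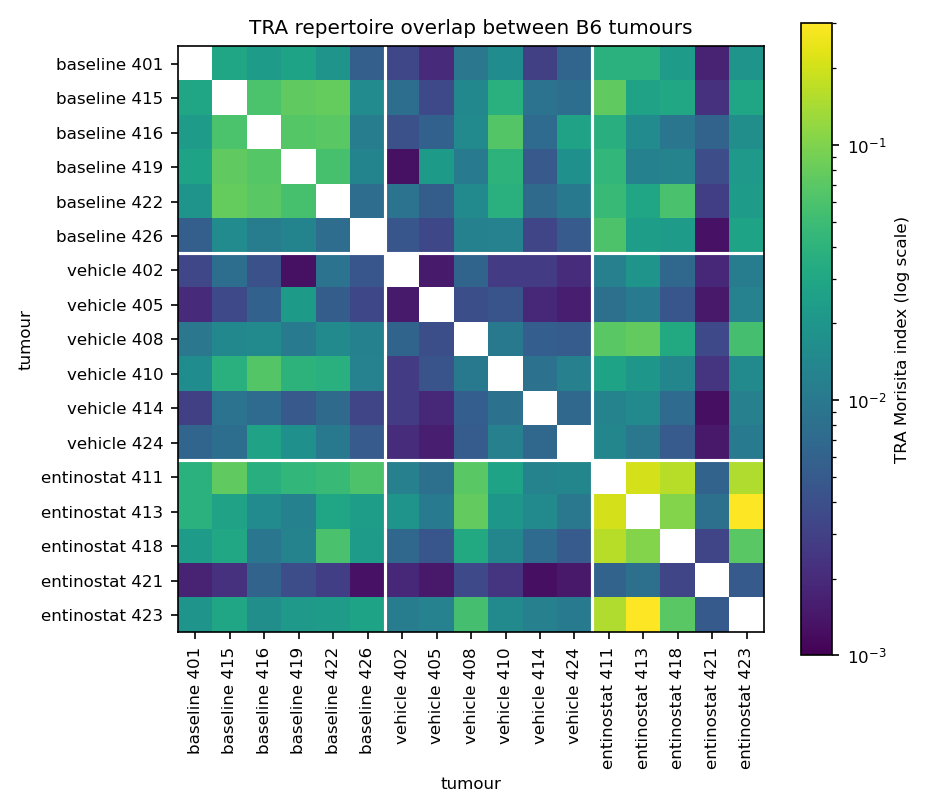
Morisita index of TRA repertoires for each pair of 17 B6 tumours ordered by group (log colour scale), with pairs of a tumour with itself left blank. Entinostat pairs averaged 0.101 and vehicle pairs 0.00500.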

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

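All tests of the epithelial pattern, the test of epithelial loss for the interferon pattern and both tests of shared library indexes were chosen after the result was seen.

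Epithelial transcripts were lower and those of macrophages, fibroblasts and T cells higher in B6 entinostat than in vehicle tumours, by lists whose calls are lost with an estimated correlation (adjusted p = 0.208 to 0.43). The fall of the basal and squamous list held under 3 other scalings between libraries, with a highest median of -8.41. These scalings moved the median of all genes only from -0.012 to between -0.162 and -0.052. That is too little to undo such a fall, so the check cannot decide on scaling in general, and the rises were not part of it. The tables argue against read depth, since the value of 1 read differed by only 0.785 (log2). A lower share of tumour epithelium as the whole cause of the rises cannot be told apart. It would raise both lists by 1 factor, and the macrophage and T cell medians lay 2.48 apart, above their summed deviations of 1.52. The macrophage minus T cell mean per library shifted by 2.41 on the log2 scale (exact two-sided permutation p = 0.0108, 462 relabelings). But that bound was set after a first one, 2 SD with no overlap, was narrowly missed by the same mean. Its SD was 1.22 among vehicle tumours (2.03 to 4.78, against 4.63 to 6.09 in entinostat tumours). A bound set on values already seen decides nothing. Whether a lower share accounts for the falls cannot be told apart, since the adhesion and luminal medians (the higher was -3.58) are part of the pattern and only restate it, and the collection volume, given for entinostat tumours alone, stays open and untested.

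The interferon gamma response list fell in B6 entinostat tumours, by a median of -1.45 (adjusted p = 0.43 with an estimated correlation). The list stayed lower under 3 other scalings, with a highest median of -1.36. These moved the median of all genes too little to decide on scaling in general. Loss of interferon-responding tumour epithelium cannot be told apart, since the fall was smaller than that of the adhesion list (difference in size of fall -3.65), as for nearly any list. Less interferon gamma transcript cannot be told apart, since Ifng had a log2 fold change of 0.0965 with an SE of 0.516. A drug effect on interferon signalling within cells was not tested.

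TRA overlap was higher among entinostat than vehicle tumours. Carry-over between libraries cannot be told apart, since all entinostat libraries carry an i5 index that no other library carries and no 2 of them share an i7 index. The 5 entinostat and baseline pairs that share an i7 index averaged 0.0222 and the other 25 pairs 0.0258 (exact one-sided permutation p = 0.736), and baseline and vehicle pairs, which share an i5 index, averaged 0.0130, but neither bears on pairs of entinostat tumours. T cell clones shared in the tissue cannot be told apart, because Trav usage in the RNA libraries followed the index with a Spearman rho of 0.685 over 10 pairs (exact one-sided permutation p = 0.075, 120 relabelings) but 2 of the 5 libraries, 421 and 413, held about 6.43 and 23.5 Trav reads, under a minimum of 30 set after the totals were seen.

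Other splits of the same tumours, 100 drawn per comparison with the real one included, asked whether chance can be excluded. It can for B6 entinostat against vehicle (1 of 100 splits with as many genes, real 9553, highest other 6550), B6 entinostat against baseline (1 of 100, real 9284, highest other 5499) and the host difference (1 of 100, real 7635, highest other 4985). For NSG vehicle against baseline no other split drawn came near the real one (1 of 100, real 2312, highest other 1). Chance is still not called excluded there, since that count rests on single libraries. For NSG entinostat against baseline (2 of 100, real 72, highest other 157) chance is not excluded, since another split gave more genes and the count also rests on single libraries. NSG libraries came from more than 1 sequencing sheet, so the splits do not tell group from batch where NSG libraries are compared. The count of 72 was 0 without NSG_Baseline_303, NSG_Baseline_304, NSG_Baseline_305, NSG_Baseline_320, NSG_Entinostat_306 or NSG_Entinostat_312, 1 without NSG_Baseline_316 or NSG_Entinostat_319, 46 without NSG_Entinostat_315 and 877 without NSG_Entinostat_327. The count of 2312 was 0 without NSG_Baseline_303, 43 without NSG_Baseline_305, 808 without NSG_Baseline_320, 1487 without NSG_Non-Treatment_311, 292 without NSG_Non-Treatment_323 and 44 without NSG_Non-Treatment_326. For B6 vehicle against baseline (100 of 100, real 0, highest other 2294) and NSG entinostat against vehicle (100 of 100, real 0, highest other 3922) the splits decide nothing, since each reaches a count of 0. The split with 3922 genes put NSG_Non-Treatment_302 and NSG_Non-Treatment_308 with NSG_Entinostat_312, NSG_Entinostat_315 and NSG_Entinostat_327, and so points to a structure of the NSG samples other than treatment. In B6 mice the split with 2294 genes put baseline 415 and 416 with vehicle 402, 408, 410 and 414, again a structure of the samples.

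The difference between entinostat and vehicle tumours differed between hosts for 7635 genes by a test of the difference. Dose and tumour volume are not stated for NSG mice, so they cannot be separated from host here. Among named genes the log2 difference, B6 minus NSG, was 11.38 for Pvalb, 10.54 for Npy, 10.40 for Ckm, 10.36 for Acta1, 2.16 for Cd3e, 2.0 for Cd274 and 1.38 for Foxp3, where Cd3e lay below the filter in NSG mice and its difference exceeds its rise of 1.48 in B6 mice. It was -9.90 for Sprr2a2, -9.81 for Krt15, -9.73 for Sprr2a3, -9.55 for Pkp1, -2.20 for Mki67 and -0.57 for Hdac1. Immune lists differed by a median of 2.0 (T cells), 1.45 (cytotoxic effectors), 2.04 (checkpoint and exhaustion), 1.39 (regulatory T cells), 4.26 (B and plasma cells), 3.85 (macrophages and monocytes), 1.17 (neutrophils), 2.33 (dendritic cells) and 1.48 (MHC class II presentation), calls lost with an estimated correlation (adjusted p = 0.236 to 0.496). NSG mice lack T, B and NK cells, and only 13 of 23 T cell, 3 of 16 cytotoxic and 5 of 13 B and plasma cell genes passed the filter there, so those differences do not show a different drug response. Stromal and other lists differed by 3.03 (mesenchymal transition), 4.13 (fibroblasts and matrix), 1.77 (endothelium), 8.27 (skeletal muscle) and 2.19 (germline and cancer testis genes), also lost with an estimated correlation (adjusted p = 0.236 to 0.496). Lower in B6 were the lists of basal and squamous genes (-7.63), luminal urothelial genes (-3.82), epithelial adhesion (-5.07), skin keratinocytes (-3.67), cell cycle (-2.21), hypoxia and glycolysis (-1.32), interferon gamma response (-1.66) and type I interferon response (-1.77). With an estimated correlation, epithelial adhesion held (adjusted p = 0.0152) and the other 7 were lost (adjusted p = 0.144 to 0.44).

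A single library lay far from the rest of its group in 42 of 686 groups of values, where chance gives about 1 in 20, or 34. Among B6 baseline tumours, B2m was low in 415 at 51610 normalized counts and Myl1 high in 415 at 950.5. Baseline 416 was low for Fgfbp1 at 1575, Gpx2 at 1125, Hdac2 at 2681 and Krt5 at 54410, and baseline 426 was low for Tnn at 3.66. Among B6 vehicle tumours, 405 was high for B3galt5 at 1269 and low for Cd3e at 38.34, Cd8a at 109.1 and Klrk1 at 26.58. Vehicle 402 was low for Cdh1 at 9827 and Gzma at 130.2, and vehicle 424 was high for H1f0 at 13970. Among B6 entinostat tumours, 423 was high for Ccr7 at 1909 and Ctla4 at 714.8 and low for Cdkn1a at 2803 and Cldn4 at 19.26. Entinostat 418 was low for Ctss at 88380 and Npy at 164.7 and high for Epcam at 878.3, Erbb2 at 448.1, Irgm1 at 4173 and Tap1 at 4930, and entinostat 411 was high for Mamdc2 at 10980.

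Among NSG baseline tumours, Esrp2 was high in NSG_Baseline_316 at 3637, Gsn low in NSG_Baseline_303 at 5329, Msr1 low in NSG_Baseline_320 at 1192 and Pvalb high in NSG_Baseline_305 at 2897. Among NSG vehicle tumours, NSG_Non-Treatment_326 was high for Bnip3 at 19100 and low for Sprr2a2 at 343.9, and NSG_Non-Treatment_311 was low for Egln3 at 11420 and Esrp2 at 2194. NSG_Non-Treatment_308 was low for Thbs2 at 2515 and Tnn at 101.4 and high for Uchl1 at 600.0, and NSG_Non-Treatment_302 had the fewest reads of its group, about 23.9 M. Among NSG entinostat tumours, NSG_Entinostat_319 was high for Hdac2 at 3294, low for Hspa1b at 3835 and had 17968 genes above 0. Cdc20 was high in NSG_Entinostat_312 at 2344 and Hdac3 low in NSG_Entinostat_327 at 3263.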

How the results depend on the processing

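The fits without muscle-rich libraries and without vehicle 402 and 424 were chosen after seeing the data. No paired analysis was possible because the groups compared share no tumour numbers, and tests on whole reads were not run. The counts for B6 entinostat against vehicle, against baseline and for the host difference stayed within 1.5 times under each alternative run, with 8685 to 9784, 8259 to 9002 and 7037 to 8082 genes when 1 library was left out. Quantile scaling put the median of all genes at -0.162, -0.134 and -0.13 in those comparisons, from -0.012, 0.01 and 0.057, and turned the majority of calls from higher to lower in all 3. Cyclic loess scaling did so in the first 2.

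For B6 vehicle against baseline, 1 gene passed with quantile scaling, 2756 with array weights and 0 to 2 with 1 library left out. For NSG entinostat against vehicle, 1 passed with array weights and 0 to 1 with 1 library left out. For NSG entinostat against baseline, 161 passed with a pseudocount of 5, about 3.2e+02 (192 higher and 124 lower) with quantile scaling, 2161 with array weights, 591 with only the groups compared, 0 at adjusted p under 0.01 and 0 to 877 with 1 library left out. For NSG vehicle against baseline, 1409 passed with no filter, 6636 with array weights, 923 at a log2 fold change of at least 1, 0 at adjusted p under 0.01 and 0 to 3262 with 1 library left out. The stricter thresholds lower a count by construction, and for the rest the cause was not tested.

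With an estimated correlation, 0 lists were called in each of the 6 comparisons within a host and 1 for the host difference, epithelial adhesion. With fry, 0 lists were called in B6 vehicle against baseline and in NSG entinostat against vehicle, and 1 in NSG entinostat against baseline. In B6 entinostat against vehicle, where 56% of all genes passed, fry kept each camera call (adjusted p up to 0.00805). It did so too for the host difference (up to 0.0145), and in B6 entinostat against baseline except for skeletal muscle (adjusted p = 0.0711). In NSG vehicle against baseline fry lost the macrophage, basal and squamous, adipocyte and skin keratinocyte lists (adjusted p = 0.0688 to 0.335). With 1 library left out, lists called numbered 24 to 26, 20 to 24 and 11 to 17 for the B6 comparisons, 2 to 12, 7 to 13 and 7 to 12 for the NSG comparisons and 19 to 24 for the host difference.

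For TRA overlap with the median over pairs, entinostat exceeded baseline within groups by 0.059, now past the threshold, and vehicle and baseline between groups gave 0.00739, no longer past it. On the log10 scale the differences were 0.986 within entinostat against vehicle, 0.114 between entinostat and vehicle and 0.0812 between vehicle and baseline, none past it. With only tumours that have RNA, vehicle and baseline between groups gave 0.00826, no longer past it. With 1 tumour left out the differences ranged from 0.0265 to 0.0703 between entinostat and baseline, 0.0216 to 0.0650 between entinostat and vehicle, 0.00464 to 0.0136 between vehicle and baseline, 0.0296 to 0.128 within entinostat against baseline, 0.0617 to 0.160 within entinostat against vehicle and -0.0455 to -0.0251 within vehicle against baseline. The cause was not tested. Depth limits genes with few reads most in NSG_Entinostat_319 and B6 entinostat 418.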

Other observations

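No test here was chosen after a result was seen, and genes of receptor segments were singled out after their values were seen.

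Neuronal and germline genes were among the lists that rose in B6 entinostat tumours, alongside those of macrophages (median log2 fold change 4.36), fibroblasts (4.73) and skeletal muscle (7.24), calls lost with an estimated correlation (adjusted p = 0.398 to 0.45). Of 18 neuronal genes measured only 7 passed the filter, and 5 of these rose. Their median log2 fold change was 3.04 (camera adjusted p = 0.0322, and adjusted p = 0.43 with an estimated correlation), with the synaptic vesicle gene Syp at 3.51 and Uchl1 at 3.59. Of 14 germline genes measured only 3 passed the filter, and all 3 rose, with a median of 2.09 (adjusted p = 0.028, and adjusted p = 0.208 with an estimated correlation), namely Tdrkh at 4.21, Piwil2 at 2.09 and Sycp3 at 2.01. The filter can be met by the entinostat tumours alone, which favours genes that are higher there, so neither list shows a broad rise. In NSG mice no member of either list passed between entinostat and vehicle, and Tdrkh was at 0.54 (adjusted p = 0.727). The host difference did not pass for the neuronal list (camera adjusted p = 0.157). It passed for the germline list (camera adjusted p = 0.0401, and adjusted p = 0.236 with an estimated correlation).

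Antibody gene segments in the RNA libraries showed some tumours, not all, led by 1 heavy chain segment. Ighv6-6 made up 73.2% of heavy chain variable signal in entinostat 418, 41.9% in entinostat 421 and 29.5% in entinostat 411, and Igkv8-19 led the kappa segments of 418 and 421 at 61.3 and 42.6%. In entinostat 423 the leading segments Ighv5-4 and Igkv4-55 held 17.2 and 17.5%. The leading heavy chain segment held 16.6% in entinostat 413 and 13.6% in baseline 416. Ighv11-2 and Igkv14-126 led in baseline 415 at 67.3 and 57.1% and in vehicle 410 at 20.6 and 27.1%, and Ighv14-4 and Igkv4-70 led in vehicle 402 at 59.5 and 71.5% (about 868 and 2020 reads). Shares are of normalized values whose whole reads are unknown, so no counting interval is given. Heavy chain signal came to about 3450 reads in entinostat 418, 87.3 in entinostat 421 and 38.6 in vehicle 410.

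Vehicle 408 and 414 were the closest pair of B6 libraries, with a median absolute deviation of 0.153 between their log2 values against 0.039 from counting alone, and both were led by Ighv1-47 and Igkv5-48, on about 16.5 and 21.8 heavy chain and 34.9 and 43.0 kappa reads. The TRA libraries of 408 and 414 had a Morisita index of 0.00545, against a mean of 0.00500 ± 0.00321 (SD) among vehicle pairs. Their mean indexes with entinostat tumours were 0.047 for 408 and 0.00971 for 414. These values argue against the same tumour behind the TRA libraries of 408 and 414. The RNA libraries are separate, and whether they came from independent tumours was not tested. Without 408 or 414 the genes passing in B6 entinostat against vehicle numbered 8954 and 9004. NSG baseline tumours carried transcripts of major urinary proteins, made mainly in liver, with Mup10 at 345.9 ± 70.38 (SD, n = 5) normalized counts in baseline and 17.14 ± 34.68 (SD, n = 5) in vehicle tumours. In B6 mice Mup10 was at 2186 ± 3205 (SD, n = 5) in entinostat and 486.9 ± 1150 (SD, n = 6) in vehicle tumours.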
